A study of Mus musculus with 15 samples.

How the data were processed

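RNA was sequenced from lung metastases of the mouse melanoma line B16-F10.1, a pigmented tumour line that colonises the lung after injection into a tail vein. Per the labels' protocols, male C57BL/6J mice aged 8 weeks received 100000 cells and were moved to a test diet after 21 days, where they stayed for 2 weeks. The labels name 4 diets by their methionine: adequate (n = 3), supplemented to 300% (n = 6), restricted to 25% (n = 3) and deficient at 0% (n = 3), which makes 15 libraries. Libraries were made from total RNA with ribosomal RNA depletion and a strand-marking kit, per the labels' protocols. The labels give no batch, date or pairing between libraries, and do not state whether each library came from a separate mouse, so p-values measure the spread between these samples.

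The deposited files hold expected counts per gene, the estimated read numbers that RSEM writes, for 37620 Ensembl gene IDs. Per the submitters' processing notes, the tools were Bowtie2 2.2.9, RSEM 1.30 and edgeR, with genome build NCBIM37. The strand setting of the counting, the annotation release and the read filters are not given in the sources used here. Reads from overlapping genes on opposite strands can therefore not be told apart, and values of gene families with near-identical copies are uncertain. Gene symbols were matched by ID to a table of gene names, which named 32897 IDs and left 4723 without a symbol. The reference at hand is of another build, so no coordinates are printed. Among 11565 genes with a total over 1000 counts, 36 IDs held the same counts in every library as another ID, which is how RSEM reports copies it cannot separate.

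Expected counts were rounded to whole numbers for testing. Total counts ran from 13107700 to 29994300 per library. Within groups, the 24 library pairs had Spearman correlations of 0.884 to 0.980 across genes, and a chi-square test of their counts gave 27.4 to 337 per degree of freedom, so no library was a repeat of another. Genes were kept with edgeR's filterByExpr on the 4 groups, which left 16001 genes, and libraries were scaled by TMM. CPM values are on that scale, and log2 CPM uses a prior count of 2.

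The main test was edgeR's quasi-likelihood test in edgeR 4.0.16 under R 4.3.3. All 15 libraries entered a single fit with a mean per diet, which shares an estimate of the spread over 11 residual degrees of freedom. The biological coefficient of variation was 0.461. From it came 5 contrasts, a test of any difference among the 4 diets, and a separate fit of a trend along the methionine rank (deficient 0, restricted 1, adequate 2, supplemented 3). P-values were adjusted by Benjamini-Hochberg at 0.05. Adjusted p-values in the report are from this test unless another tool is named. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run beside it.

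Gene lists were fixed before the data were examined: 32 lists with 897 entries, of which 889 matched an ID and 858 were tested. They cover amino acid and methionine metabolism, stress, cell cycle, immune and interferon genes, and markers of lung, blood, vessel, muscle and melanocyte cells. Lists were tested in each contrast with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes. Fry's directional p asks whether the list's genes move one way on balance, and compares nothing with other genes. For each list the number of members passing when adjusted over the list alone is given beside the number passing over all genes tested. Exact permutation tests of list levels are two-sided. With 3 libraries against 3 their p cannot go below 0.1, and with 3 against 6 not below 0.0119.

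The genes named follow a rule fixed before the data were examined. It takes up to 6 called genes with the highest and 6 with the lowest log2 fold change, having a mean log2 CPM of at least 1, a symbol and non-overlapping libraries. It adds up to 3 members with the smallest p from each list with a call. Where under 5 genes pass, it takes the 6 genes with the smallest p and a mean log2 CPM of at least 1, given as values. It always takes Asns, Trib3, Mat2a, Tyr, Mki67 and Sftpc. Members of the lists with the smallest camera p are given first, and members of the remaining lists are left out. Some genes the rule takes are not described here.

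The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among the 16001. For the deficient and adequate groups, edgeR recovered 20% of the 2-fold and 70% of the 4-fold genes with 2 unchanged genes called, and DESeq2 41% and 82% with 39 unchanged genes called. For the supplemented and adequate groups, edgeR recovered 25% and 81%, and DESeq2 44% and 88% with 33 unchanged genes called. For the deficient and restricted groups, edgeR recovered 26% and 76%. In a simulated shift of a list between the deficient and adequate groups, camera with either correlation and fry all recovered it and called 0 of 31 other lists. Genes were drawn independently there, so this cannot show how often lists of correlated genes are called without a shift. In the real data for that contrast, estimated correlations ran from 0.00667 (lipid oxidation) to 0.830 (alveolar type 1).

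Alternatives planned before the data were examined were RLE factors, library totals without TMM, DESeq2, limma-voom, no filter on low counts, a filter of CPM at least 1 in 3 libraries, unrounded expected counts, a covariate for the level of lung alveolar markers, fits of the compared groups alone and leaving out each library. Leaving out adequate replicate 1, supplemented replicate 5 and deficient replicate 3 together was added after seeing the data. A contrast of the adequate group against the mean of the other 3 diets was also added then. Floors of 3 counts and intervals cover counting error only.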

Results

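The series holds 15 transcriptomes of melanoma lung metastases from mice fed diets that differ in methionine, an essential amino acid and the source of the methyl donor S-adenosylmethionine. The design text names the adequate, restricted and deficient diets. The supplemented group is known from the sample labels alone. Libraries held 18836100 to 23006300 counts in the adequate group, 13107700 to 26362700 in the supplemented, 15209500 to 20687400 in the restricted and 13714700 to 29994300 in the deficient group.

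The libraries differed widely in markers of normal lung. The alveolar type 2 list, genes of the surfactant-making cells, had a mean log2 CPM of 0.47 in supplemented replicate 5 and 7.58 in deficient replicate 3. Sftpc, which encodes surfactant protein C, stood at 0.186 CPM in supplemented replicate 5 and 2159 CPM in deficient replicate 3. The muscle genes Acta1, Ckm and Myh4 reached 845.5, 151.8 and 172.9 CPM in supplemented replicate 5, against at most 3.096, 5.355 and 0.0722 CPM in the other libraries. The pigment enzyme gene Tyr ran from 361.6 CPM in deficient replicate 3 to 815.2 CPM in adequate replicate 3. In adequate replicate 1, small structural RNAs took 43.9% of counts, against 13.8% to 28.8% elsewhere, and its TMM factor was 0.69. The first principal component held 30.3% of the variance. Its correlation with list levels was 0.963 for alveolar type 1, 0.94 for endothelial, 0.925 for alveolar type 2 and 0.825 for fibroblast and matrix. It was 0.808 for macrophages, 0.775 for antigen presentation, 0.277 for interferon, 0.262 for melanocyte pigment and -0.721 for G2/M.

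**Figure D1:**
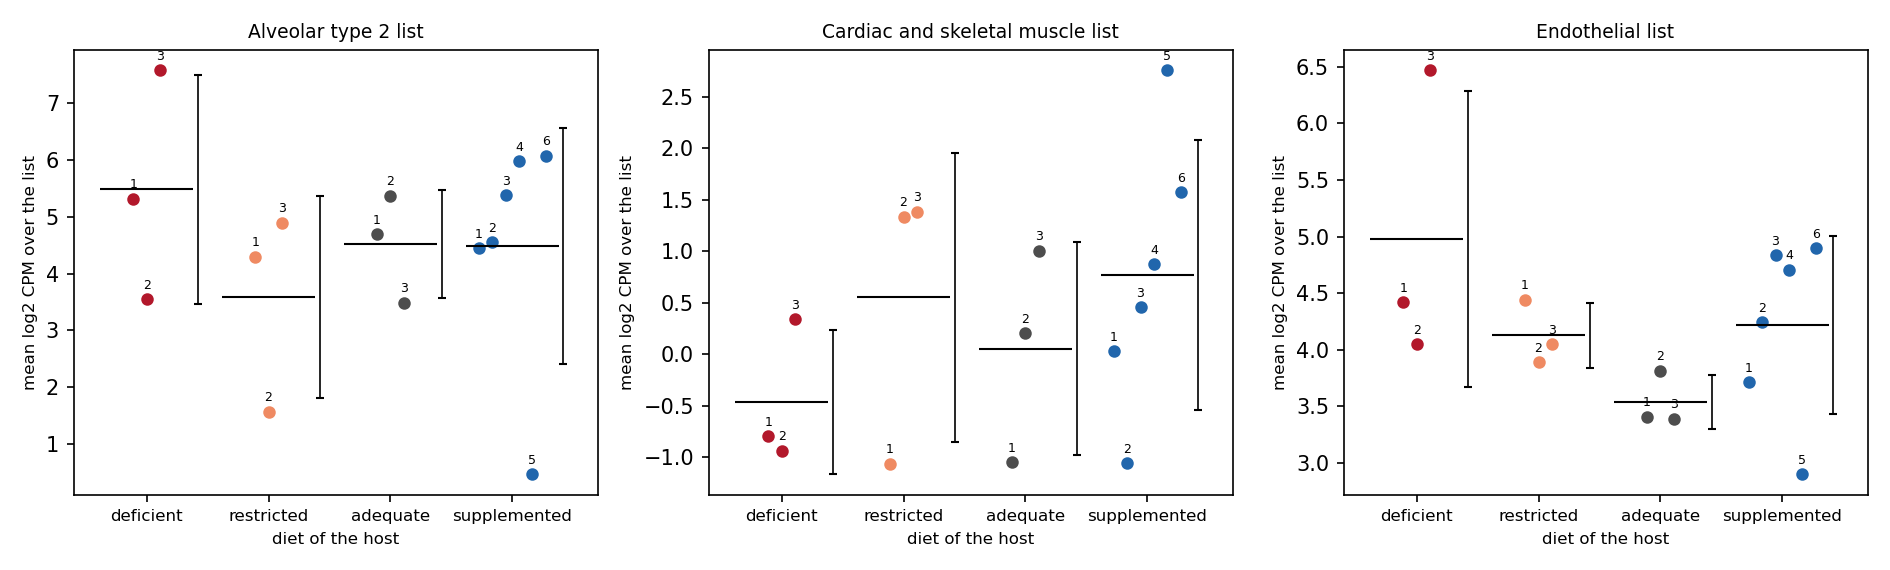
Mean log2 CPM of the alveolar type 2, muscle and endothelial lists (vertical axes) in each library (numbered points) by diet, with horizontal lines as group means and bars as SD. Deficient replicate 3 has the highest alveolar type 2 level, 7.58, and supplemented replicate 5 the lowest, 0.47, with the highest muscle level, 2.76.

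The first comparison asks how tumours under a diet without methionine differed from those under an adequate diet. Ddr2, a collagen-binding receptor tyrosine kinase (ENSMUSG00000026674), rose from 58.0 ± 8.81 CPM (SD, n = 3) in adequate to 133.8 ± 3.8 CPM (SD, n = 3) in deficient libraries, a log2 fold change of 1.21 (SE 0.169, edgeR adjusted p = 0.0435). The interferon list lay higher in the deficient libraries, with 36 of 37 members above 0 and a median log2 fold change of 0.80 (camera adjusted p = 3.11e-14, adjusted p = 0.417 with an estimated correlation), and its median was 1.28, 0.55 and 0.63 without adequate replicates 1, 2 and 3. The endothelial list had a median of 1.98 with 27 of 28 members above 0 (camera adjusted p = 8.73e-14, adjusted p = 0.417 with an estimated correlation). The fibroblast and matrix list had a median of 1.04 with 33 of 34 members above 0 (camera adjusted p = 8.61e-13, adjusted p = 0.109 with an estimated correlation), and was the list fry called (adjusted p = 0.0262). The nuclear oxidative phosphorylation list was lower, at a median of -0.45 with 39 of 40 members below 0 (camera adjusted p = 7.31e-13, adjusted p = 0.417 with an estimated correlation).

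No list member passed over all genes, so the following are values. Among interferon genes, Parp14 had a log2 fold change of 1.14 (SE 0.272, adjusted p = 0.149), Oasl2, an oligoadenylate synthetase-like gene, 1.36 (SE 0.332) and Zbp1, a sensor of Z-form nucleic acid, 1.98 (SE 0.523). 13 members passed adjusted over the list alone and DESeq2 called 9. Of the endothelial genes, Robo4 stood at 7.20 ± 2.50 CPM (n = 3) in adequate and 32.9 ± 16.2 CPM (n = 3) in deficient libraries, and 24 of 28 members passed adjusted over the list alone. Deficient replicate 3 had an endothelial level of 6.47, against 4.42 and 4.05 in the other deficient libraries. Lung lists moved the same way as these cell type lists: alveolar type 1 with a median of 2.33 and 16 of 17 members above 0, airway with 3.19 and 18 of 19, and alveolar type 2 with 1.87 and 19 of 22 (camera adjusted p = 0.00255, 0.0152 and 0.0292, adjusted p = 0.716 with an estimated correlation for each). Without deficient replicate 3 the alveolar type 2 list turned (camera adjusted p = 0.459), and without adequate replicate 3 its adjusted p was 0.464. The matrix genes Col12a1, Col6a3 and Col14a1 had log2 fold changes of 1.47, 1.45 and 1.39, and 13 members passed adjusted over the list alone. In the antigen presentation list (camera adjusted p = 2.77e-11, adjusted p = 0.417 with an estimated correlation), the peptide transporter gene Tap2 went from 24.2 ± 1.42 to 46.9 ± 5.74 CPM and 13 of 25 members passed adjusted over the list alone. Ndufa8, a subunit gene of respiratory complex I, had a log2 fold change of -0.66 (SE 0.166). Adequate replicate 1, the library rich in structural RNA, had the highest level of the oxidative phosphorylation list, 7.36 against 6.70 in both other adequate libraries. Without adequate 1, supplemented 5 and deficient 3 together that list had a camera adjusted p = 0.30.

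Other genes with the smallest p were Sap18b (log2 fold change -1.27, SE 0.199, adjusted p = 0.0816), Mfsd12, a lysosomal transporter that affects pigmentation (1.06, SE 0.188, adjusted p = 0.149), and the unnamed ENSMUSG00000075752 (-2.30, SE 0.419, adjusted p = 0.149). The amino acid response list, targets of the pathway that senses uncharged tRNA, had a median of -0.03 with 21 of 45 members above 0 (camera adjusted p = 0.574). In this comparison 0 members passed and 3 had an unadjusted p under 0.05. Without deficient replicate 3 its median was 0.16 with 32 of 45 members above 0 (camera adjusted p = 0.00327, adjusted p = 0.617 with an estimated correlation). Without deficient replicate 1 it was lower instead (camera adjusted p = 0.0448), so the direction rests on which deficient library is left out. Asns, asparagine synthetase, stood at 127.7 ± 31.4 CPM in adequate and 140.3 ± 89.95 CPM in deficient libraries, and Trib3 at 56.8 ± 7.93 and 48.1 ± 26.0 CPM (n = 3 each). Mat2a, which makes S-adenosylmethionine, had a log2 fold change of -0.49 (SE 0.276, adjusted p = 0.411), Tyr -0.40 (SE 0.224), Mki67 0.57 (SE 0.301) and Sftpc 2.15 (SE 1.61). edgeR called 1 gene, with 2422 at an unadjusted p under 0.05 where chance gives 800. Limma-voom called 1 and DESeq2 588 (429 higher). The Ddr2 call was lost without any of adequate replicate 2 or 3 or deficient replicate 1, 2 or 3 (adjusted p = 0.138, 0.0616, 0.145, 0.0789 and 0.165), with the log2 fold change between 1.09 and 1.29 over all left-out libraries, and 4 genes were called without adequate replicate 1. It was also lost without a filter on low counts (adjusted p = 0.0540), and edgeR called 0 genes with the lung covariate (2021 at an unadjusted p under 0.05) and with these 2 groups alone (1326).

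**Figure D2:**
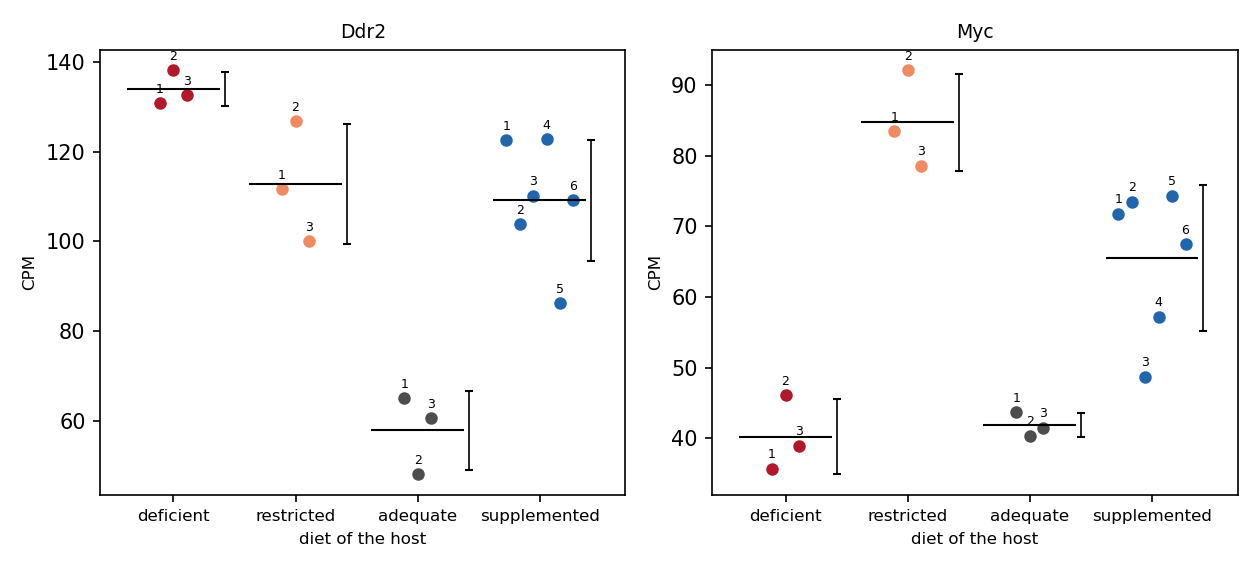
CPM of Ddr2 and Myc in each library (numbered points) by diet, with horizontal lines as group means and bars as SD. Ddr2 is lowest in the 3 adequate libraries, and Myc averages 84.7 CPM in the restricted and 40.3 CPM in the deficient libraries.

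The second comparison sets the restricted diet against the adequate diet. The interferon list was higher in restricted libraries, with 37 of 37 members above 0 and a median of 0.86 (camera adjusted p = 5.54e-29, adjusted p = 0.159 with an estimated correlation), and 20 members passed adjusted over the list alone. Irgm2, an interferon-induced GTPase gene, stood at 32.2 ± 9.73 CPM in adequate and 82.0 ± 23.2 CPM in restricted libraries (n = 3 each), Stat2, a transducer of interferon signals, at 21.8 ± 6.06 and 55.3 ± 14.1 CPM, and Ddx58, the RNA sensor RIG-I, at 86.6 ± 6.88 and 166.5 ± 37.3 CPM. The G2/M and mitosis list had a median of 0.37 with 35 of 40 members above 0 (camera adjusted p = 4.83e-08, adjusted p = 0.537 with an estimated correlation), where Kif2c had 0.69 (SE 0.215), Tpx2 0.62 (SE 0.193) and Mki67 0.83 (SE 0.302, adjusted p = 0.434). In the same comparison the endothelial list was higher, with a median of 0.73 and 21 of 28 members above 0 (camera adjusted p = 0.000203, adjusted p = 0.567 with an estimated correlation). Camera called 3 cell type lists lower: alveolar type 2 with a median of -0.58 and 15 of 22 members below 0, erythroid and platelet with -1.47 and 11 of 13, and neutrophil with -1.50 and 12 of 14 (camera adjusted p = 0.0178, 0.000803 and 0.00147, adjusted p = 0.767, 0.530 and 0.537 with an estimated correlation). The alveolar type 2 call was lost without adequate replicate 1 (0.0586), adequate replicate 2 (0.423) or restricted replicate 2 (0.785). Over the 15 libraries the G2/M list ran against the alveolar type 2 list (r = -0.706, permutation p = 0.00542, adjusted p = 0.014, rho = -0.761, p = 0.00146), a relation looked at after the data were seen, and with the lung covariate its camera adjusted p was 0.000129. The fibroblast and matrix list had a median of 0.70 with 28 of 34 members above 0 (camera adjusted p = 9.17e-08, adjusted p = 0.159 with an estimated correlation). Its Col15a1 had 1.74 (SE 0.359), Fbln1 1.33 and Thy1 1.93.

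Klf15, a transcription factor induced by glucocorticoids, stood at 78.6 ± 18.0 CPM in adequate and 23.03 ± 3.35 CPM in restricted libraries, a log2 fold change of -1.77 (SE 0.282, adjusted p = 0.102). Myc had a log2 fold change of 1.02 (SE 0.175, adjusted p = 0.114), Mfsd12 1.12, Ddr2 0.96 and Tap2 0.97. The ribosomal protein and oxidative phosphorylation lists were lower, at medians of -0.34 and -0.32 (camera adjusted p = 8.55e-07 and 1.05e-06, adjusted p = 0.567 with an estimated correlation for both). Without adequate replicate 1 their camera adjusted p was 0.379 and 0.490. Asns, Trib3, Mat2a, Tyr and Sftpc had log2 fold changes of -0.09, -0.18, -0.04, -0.18 and -1.07. edgeR called 0 genes (smallest adjusted p = 0.102), with 1468 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 131 (85 higher). With the lung covariate edgeR called 37 genes, and 5 and 2 genes without adequate replicate 1 and adequate replicate 3.

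**Figure D3:**
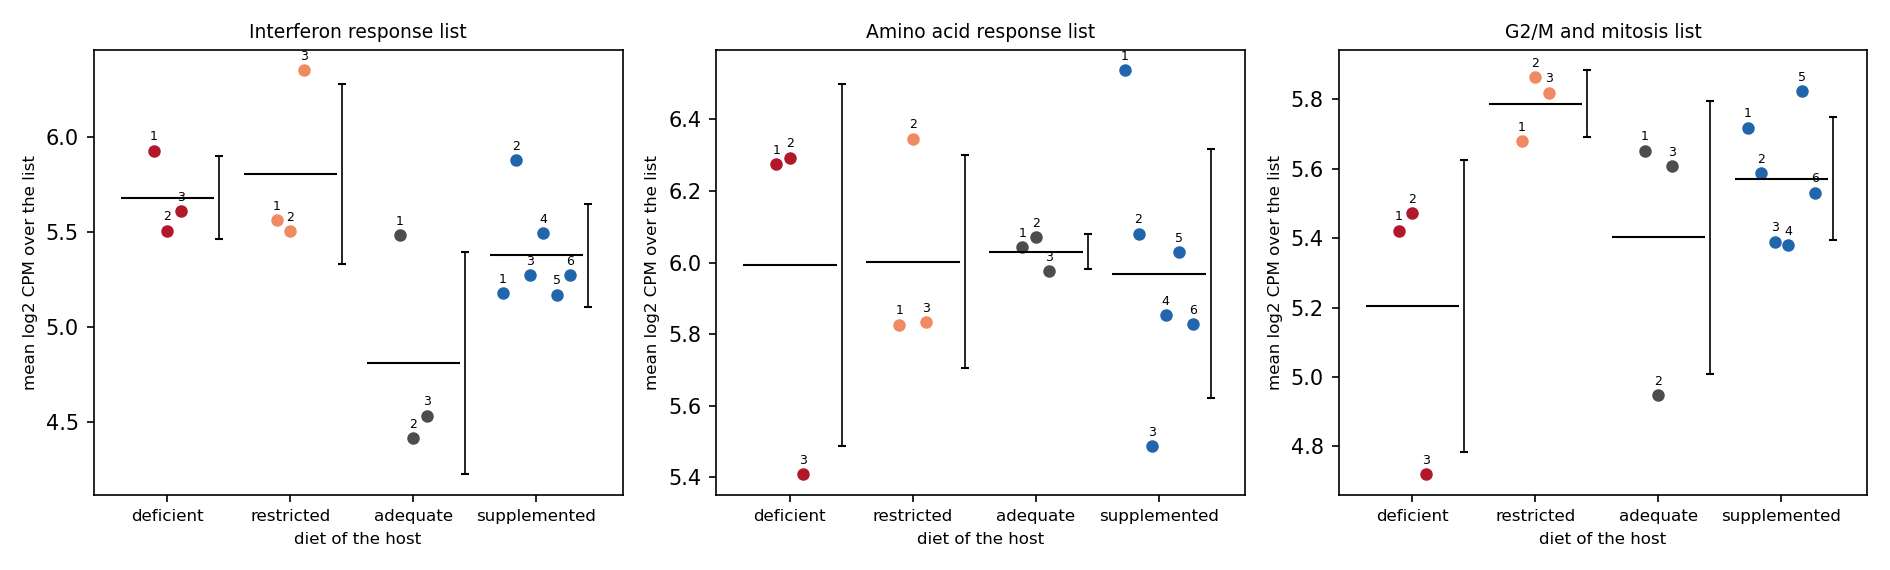
Mean log2 CPM of the interferon, amino acid response and G2/M lists (vertical axes, not starting at 0) in each library (numbered points) by diet, with horizontal lines as group means and bars as SD. Adequate replicates 2 and 3 have interferon levels of 4.41 and 4.53, below the other 13 libraries, and deficient replicate 3 has the lowest amino acid response and G2/M levels, 5.41 and 4.72.

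The third comparison sets the supplemented diet against the adequate diet. The interferon list was again higher, with 34 of 37 members above 0 and a median of 0.52 (camera adjusted p = 4.31e-11, adjusted p = 0.672 with an estimated correlation). The median was 0.95 without adequate replicate 1, 0.29 without adequate replicate 2 and 0.33 without adequate replicate 3. 6 members passed adjusted over the list alone. Stat2 stood at 41.2 ± 5.47 CPM (n = 6) against 21.8 ± 6.06 CPM (n = 3), Parp14 at 61.8 ± 12.7 against 32.5 ± 5.63 CPM, and Ddx58 at 131.9 ± 19.9 against 86.6 ± 6.88 CPM. The fibroblast and matrix list had a median of 0.59 with 31 of 34 members above 0 (camera adjusted p = 2.14e-09, adjusted p = 0.257 with an estimated correlation). Col12a1, Col6a3 and Tnc had log2 fold changes of 1.55 (SE 0.314), 1.25 (SE 0.311) and 2.16 (SE 0.538). The endothelial list had a median of 0.88 with 27 of 28 members above 0 (camera adjusted p = 5.26e-06, adjusted p = 0.672 with an estimated correlation), with Robo4 at 1.46, Aplnr at 1.44 and Nos3 at 1.11. The ribosomal protein list had a median of -0.41 with 37 of 37 members below 0 (camera adjusted p = 3.96e-11, adjusted p = 0.672 with an estimated correlation), with Rpl19, Rps23 and Rps24 at -0.64, -0.49 and -0.67. Its level was 8.85 in adequate replicate 1, 8.09 and 8.05 in adequate replicates 2 and 3, and 7.95 on average in supplemented libraries. Leaving out each library in turn, its camera adjusted p reached 0.0438. The oxidative phosphorylation list had a median of -0.33 (camera adjusted p = 7.88e-11, adjusted p = 0.672 with an estimated correlation), with Ndufa8, Ndufa4 and Cox7c at -0.47, -0.69 and -0.66. Without adequate replicate 1 its camera adjusted p was 0.0789.

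Ddr2 had a log2 fold change of 0.91 (SE 0.150, adjusted p = 0.146), Unc13b 1.17 (SE 0.220), Prpf40b 0.88 (SE 0.173) and the unnamed ENSMUSG00000064447 -1.76 (SE 0.350). Alb, which encodes serum albumin (edgeR adjusted p = 0.201), had 364, 259 and 87 counts in the adequate libraries. 5 of the 6 supplemented libraries held 0 counts. Asns, Trib3, Mat2a, Tyr, Mki67 and Sftpc had log2 fold changes of -0.09, -0.41, -0.10, -0.27, 0.76 and 0.54. edgeR called 0 genes, with 1563 at an unadjusted p under 0.05. Limma-voom called 3 and DESeq2 137 (85 higher).

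The fourth comparison sets the deficient diet against the restricted diet, the pair with the least methionine. The G2/M and mitosis list was lower in deficient libraries, with 40 of 40 members below 0 and a median of -0.53 (camera adjusted p = 9.53e-25, adjusted p = 0.288 with an estimated correlation). Kif2c, Knstrn and Plk1, genes of the mitotic spindle, had log2 fold changes of -0.73 (SE 0.215), -0.88 (SE 0.265) and -0.80 (SE 0.247). The melanocyte pigment list moved the same way, with 22 of 28 members below 0 and a median of -0.295 (camera adjusted p = 7.83e-05, adjusted p = 0.352 with an estimated correlation). The cholesterol synthesis list had a median of -0.62 with 20 of 23 members below 0 (camera adjusted p = 1.55e-15, adjusted p = 0.243 with an estimated correlation), and 8 members passed adjusted over the list alone. Dhcr7, Fdft1 and Sqle had -0.90 (SE 0.230), -0.97 (SE 0.251) and -0.85 (SE 0.250). Myc stood at 84.7 ± 6.84 CPM in restricted and 40.3 ± 5.35 CPM in deficient libraries (n = 3 each), a log2 fold change of -1.07 (SE 0.175, adjusted p = 0.270).

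The macrophage and alveolar type 1 lists were higher in the deficient libraries, with their largest levels in deficient replicate 3. The macrophage list had a median of 0.99 with 29 of 30 members above 0 (camera adjusted p = 1.83e-10, adjusted p = 0.288 with an estimated correlation), with Fcgr3, Lyz2 and Tyrobp at 1.28, 2.52 and 1.18. Lyz2 also belongs to the alveolar type 2 list, which had a median of 2.53 in this comparison. The alveolar type 1 list had a median of 3.005 with 17 of 17 members above 0 (camera adjusted p = 6.69e-09, adjusted p = 0.352 with an estimated correlation). The hypoxia and glycolysis list had a median of -0.46 with 29 of 36 members below 0 (camera adjusted p = 1.77e-08, adjusted p = 0.352 with an estimated correlation), with Bnip3l, Pdk1 and Aldoc at -0.65, -0.75 and -0.97. Its level was 6.23 in deficient replicate 3. Deficient replicates 1 and 2, at 7.12 and 7.34, lay within the restricted range of 7.02 to 7.57. Sema3c, a secreted guidance factor, had 2.79 (SE 0.574, adjusted p = 0.649), Cdca2 -0.97 (SE 0.213), 4931406C07Rik -0.92 (SE 0.202), Ogn 4.15 (SE 0.926) and Sap18b -0.88 (SE 0.198). The amino acid response list had a median of -0.03 (camera adjusted p = 0.302), and 0.21 without deficient replicate 3 (camera adjusted p = 0.000225, adjusted p = 0.785 with an estimated correlation). It was lower without deficient replicate 1, deficient replicate 2 or restricted replicate 3 (camera adjusted p = 0.0137, 0.0135 and 0.0314). Asns, Trib3, Mat2a, Tyr, Mki67 and Sftpc had log2 fold changes of 0.23, -0.06, -0.45, -0.22, -0.26 and 3.22. edgeR called 0 genes, with 1191 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 9 (6 higher).

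The fifth comparison sets the extremes, deficient against supplemented. The G2/M list had a median of -0.34 with 40 of 40 members below 0 (camera adjusted p = 2.87e-15, adjusted p = 0.268 with an estimated correlation), with Kif20a, Birc5 and Knstrn at -0.44, -0.58 and -0.53. Without deficient replicate 3, supplemented replicate 5 and adequate replicate 1 its camera adjusted p was 0.107. The cholesterol synthesis list had a median of -0.31 with 21 of 23 members below 0 (camera adjusted p = 6.12e-08, adjusted p = 0.268 with an estimated correlation), with Stard4, Fdft1 and Dhcr7 at -0.50, -0.51 and -0.47. The antigen presentation list had a median of 0.58 with 23 of 25 members above 0 (camera adjusted p = 1.39e-09, adjusted p = 0.268 with an estimated correlation), with Erap1, H2-DMb1 and H2-D1 at 0.71, 0.79 and 0.54. The macrophage list had a median of 0.64 (camera adjusted p = 6.12e-08, adjusted p = 0.268 with an estimated correlation), with Mertk, Tyrobp and Csf1r at 0.75, 0.91 and 0.92. The endothelial list had a median of 1.10 with 28 of 28 members above 0 (camera adjusted p = 3.62e-11, adjusted p = 0.268 with an estimated correlation), with Ramp2, Plvap and Tek at 1.44, 1.12 and 2.27. Without deficient replicate 3 it turned to the other direction (camera adjusted p = 0.803). Lung lists were higher as well: alveolar type 1 with a median of 1.56 and 17 of 17 members above 0, airway with 2.36 and 19 of 19, and alveolar type 2 with 1.43 and 20 of 22 (camera adjusted p = 3.70e-06, 2.27e-05 and 0.000244, adjusted p = 0.495, 0.495 and 0.583 with an estimated correlation). Without deficient replicate 3 both alveolar lists turned (camera adjusted p = 0.169 for each).

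Myc had a log2 fold change of -0.70 (SE 0.155, adjusted p = 0.870), Sap18b -0.76, Scamp3 -0.67, Sema3c 1.85, Plcg2 0.84 and Cxcl12, a chemokine that binds CXCR4, 1.86 (SE 0.456). Asns, Trib3, Mat2a, Tyr, Mki67 and Sftpc had log2 fold changes of 0.22, 0.17, -0.38, -0.13, -0.18 and 1.62. edgeR called 0 genes, with 872 at an unadjusted p under 0.05 where chance gives 800. Limma-voom and DESeq2 called 0.

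Over the 5 comparisons, with 32 lists tested in each, camera made 91 calls at the preset correlation and 0 with an estimated correlation, and fry made 1. Exact permutation tests of list levels called none after adjustment over the lists of a comparison (smallest adjusted p = 0.381). With 3 libraries against 3 that outcome was fixed in advance. In the 5 comparisons 0 list members passed over all genes tested. The methionine cycle and transsulfuration list, which holds Mat2a, was not called in any of the 5 (camera adjusted p = 0.592, 0.472, 0.460, 0.994 and 0.887 in the order above).

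The test of any difference among the 4 diets called 1 gene with edgeR, with 1516 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 270. Without adequate replicate 1 edgeR called 0 genes, and likewise without supplemented replicate 4, restricted replicate 1, 2 or 3, or deficient replicate 1. The trend along the methionine rank called 0 genes with edgeR (smallest adjusted p = 0.438), with 556 at an unadjusted p under 0.05, fewer than the 800 chance gives. DESeq2 and limma-voom called 0.

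Fold changes against the shared adequate libraries moved together across genes, which are not independent replicates. The deficient and supplemented effects correlated at 0.707, where 20 simulations of unchanged groups gave 0.583, and their covariance was 0.629 against 0.345. The restricted effects correlated with the deficient at 0.517 (simulated 0.499, covariance 0.497 against 0.344) and with the supplemented at 0.644 (simulated 0.584, covariance 0.463 against 0.346). At an unadjusted p under 0.05, 470 genes were higher and 441 lower in both deficient and supplemented libraries, against 136.6 and 68.9 simulated and 72.1 and 46.0 for independent lists. The 3 adequate libraries do not make 2 parts of at least 2 libraries each and no split of them was run, so part of the excess may come from them. The simulated genes were also drawn unchanged and independently, while genes in the real data were correlated. In the real data 2422 (deficient) and 1563 (supplemented) genes had an unadjusted p under 0.05, where chance gives 800. The simulated counts of shared genes are therefore not a like comparison, and the excess cannot be assigned to a shared effect of the diets.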

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

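Of 61 list levels, named genes and library measures compared within the supplemented group, 7 had a library far from the other 5, where chance gives about 3 (1 in 20). Groups of 3 were not tested. Tests chosen only after the result was seen were those of lung tissue and diet for the lung markers, of a single adequate library and a graded response for the interferon list, and of liver RNA. The test of clock genes was set before their values were seen, apart from Per1.

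Supplemented replicate 5 held 5 of the 7. Its alveolar type 1 list level was 0.597 (next lowest 4.16), its alveolar type 2 level 0.466 (next 4.45), its melanoma dedifferentiation level 3.71 (next 4.70), its level of mitochondrially encoded genes 6.39 (next 7.70) and its log2 CPM of Sftpc -1.79 (next 6.79). In supplemented replicate 3 the log2 CPM of Alb was -1.11 (others -3.28), from 5 counts. In supplemented replicate 6 the log2 CPM of Ogn was 3.63 (next 2.53).

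The first pattern weighed is the wide spread of lung markers between libraries of the same diet. Diet is argued against as the main source, since libraries of the same diet already differed widely in the alveolar type 2 list, with a mean SD within diets of 1.71. The diet means had an SD of 0.775, no wider than reassigned libraries give (permutation p = 0.688). Means vary less than single libraries and the groups are small, so a lesser part of diet is not excluded. Library depth is argued against too, as the list correlated with log2 total count at 0.018. Lung tissue carried along with the metastasis may account for it: within diets the airway and endothelial lists both followed the alveolar type 2 list, the smaller correlation being 0.854. A biological difference in how far tumours had replaced the lung was not tested.

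The second pattern is the higher mean of the interferon list in the 3 test diets than in adequate, which rests on adequate replicates 2 and 3 (levels 4.41 and 4.53), as adequate replicate 1 (5.48) lies within the range of the test diets. With the lung covariate the smallest of the 3 medians was 0.508 (0.516 without it), which argues against carried-along lung as the whole cause. Leaving out each adequate library in turn left a smallest median of 0.291, which argues against a single adequate library as the whole cause, while leaving out adequate replicate 1 raised the medians from 0.80, 0.86 and 0.52 to 1.28, 1.28 and 0.95 (deficient, restricted, supplemented). A graded response to methionine could not be ruled in or out: the diet means (deficient 5.68, restricted 5.81, adequate 4.81, supplemented 5.38) do not follow its order, while the supplemented level lay above the adequate level with an exact permutation p = 0.0714, and the deficient and restricted levels at 0.1, the smallest 3 against 3 allows. Adjusted over the lists, the permutation p was 0.428 for supplemented, 0.4 for deficient and 0.457 for restricted. A hypothesis that adequate libraries were collected or handled apart from the rest could not be tested from the labels.

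The third pattern, on 2 genes chosen after their values were seen, is that Alb was higher in each adequate library than in the other diets (3.96 to 22.9 CPM against at most 1.55), and Cirbp in adequate replicates 2 and 3 (41.3 and 44.7 CPM), but not in adequate replicate 1 (13.7 CPM, others 5.92 to 17.8). Rbm3 and Klf15, also looked at afterwards, were higher in each adequate library, replicate 1 included. Rbm3 stood at 517 to 558.2 CPM against at most 430.7 CPM, and Klf15 at 63.94 to 98.76 CPM against at most 52.8 CPM. A different time of day of collection was neither borne out nor excluded. Of 13 measured clock genes 1, Per1, had an unadjusted p under 0.05, where the share over all genes would give 1.83. Arntl and Dbp did go in opposite directions, as a clock shift would give, but by 0.29 and -0.39, neither among the genes under that threshold. The contrast averaged the 3 adequate libraries, while Cirbp was higher in adequate replicates 2 and 3 alone. Its SE was 0.406 for Dbp and 0.868 for Per2, so moderate shifts could be missed. Carried-along lung is argued against for Cirbp, whose smallest absolute log2 fold change was 1.34 with the lung covariate and 1.41 without. Liver RNA as a candidate source of Alb cannot be told apart from other sources. Of 20 liver genes, 6 were higher in every adequate library: Alb itself, Fga, Fgb, Fgg, Serpina1a and Serpina3k. Serpina1a stood at 2.961, 1.555 and 0.818 CPM in adequate replicates 1, 2 and 3, and at 0 CPM in all libraries of the other diets. The remaining 14 did not separate, among them Ahsg (at most 5.92 CPM in adequate, 6.64 in supplemented replicate 3 and 6.52 in deficient replicate 2), Hp, Apoa1, Apob, Ttr, Cyp2e1 and Trf. Some of the 14 overlapped through adequate replicate 3 alone, such as Hpx, Tat and Serpinc1, all at low values. They stood there at 0.637, 0.182 and 0.182 CPM, against at most 0.986, 0.276 and 0.219 CPM in the other diets.

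Other splits of the same libraries were counted for each test. The deficient against adequate split called 1 gene, and the highest of the other 9 called 0. At an unadjusted p under 0.05 the values were 2422 and 2455, with 2 of 10 splits as high. For restricted against adequate 1 of 10 splits reached the real 1468 genes at an unadjusted p (highest other 1005), and for deficient against restricted 3 of 10 reached 1191 (highest other 1712). In these 3 comparisons 10 splits are too few for a share under 0.05. At an unadjusted p, chance could not be excluded for supplemented against adequate, where 8 of 84 splits reached 1563 (highest other 3069), nor for deficient against supplemented, where 36 of 84 reached 872 (highest other 2780), nor for the methionine rank, where 57 of 100 draws reached 556 (highest other 3056).

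Where edgeR called 0 genes, every split reaches that count, so it says nothing about chance: 10 of 10 for restricted against adequate and for deficient against restricted (highest other 0 in both), 84 of 84 for supplemented against adequate (highest other 0) and for deficient against supplemented (highest other 1), and 100 of 100 for the methionine rank (highest other 2). The counts at an unadjusted p under 0.05 are those just given, and DESeq2 called 131, 9, 137, 0 and 0 genes and limma-voom 0, 0, 3, 0 and 0 in that order. Of 100 draws over the 4 diets, the real grouping included, 2 called at least 1 gene, a share under 0.05. An adjusted p under 0.05 is itself meant to be rare by chance, so this share adds little to that call. The call was also lost with limma-voom and without some single libraries, so chance is not excluded. The highest other draw called 127 genes, which may point to a structure of the samples apart from diet, and how that draw grouped the libraries was not examined. At an unadjusted p 11 of 100 draws reached 1516 (highest other 2419), so chance could not be excluded for that count.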

How the results depend on the processing

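The alternative without 3 libraries was chosen after seeing the data. The cause of each change below was not tested unless stated. DESeq2 called 588 genes (deficient against adequate), 131 (restricted against adequate), 137 (supplemented against adequate), 9 (deficient against restricted) and 270 (4 diets), against 1, 0, 0, 0 and 1 with edgeR. On simulated data it also called more unchanged genes. limma-voom called 3 genes for supplemented against adequate and 0 for the 4 diets. Without a low-count filter edgeR called 0 for deficient against adequate and 8 for the 4 diets, and with library totals 2 for supplemented against adequate and 2 for the 4 diets. The lung covariate gave 0 for deficient against adequate, 37 for restricted against adequate and 2 for the 4 diets. With only the deficient and adequate libraries, fewer samples, 0 were called. Without adequate 1, supplemented 5 and deficient 3 together, 5, 66, 2 and 3 were called for deficient, restricted and supplemented against adequate and for the 4 diets. Leaving out each library gave 0 to 4 genes for deficient against adequate, 0 to 5 for restricted against adequate, 0 to 2 for the 4 diets and 0 to 0 for the remaining tests. The other alternatives gave the same counts of genes. Library totals without TMM moved the median log2 fold change of all genes by 0.13, 0.14 and 0.20 in the 3 comparisons with adequate.

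Camera called 91 lists, 0 with an estimated correlation and 1 with fry, 90 with RLE factors, 92 with library totals, 75 with the lung covariate, 81 without the 3 libraries and 83 to 101 when leaving out each library. Directions turned as follows among lists called before or after the change, with camera adjusted p. With the lung covariate, the alveolar type 2 list turned in deficient against adequate (0.189), restricted (0.391) and supplemented (0.326), which says nothing as the covariate is built from it and the type 1 list. The amino acid response list turned in deficient against restricted (0.0252). That list also turned, with no call in either fit, in deficient against adequate (0.529) and supplemented (0.0559). Without the 3 libraries, in deficient against adequate the ribosomal (0.318), amino acid response (0.0138), alveolar type 2 (0.551) and G2/M (0.0539) lists turned. In deficient against restricted the amino acid response list turned (0.000781). In deficient against supplemented those that turned were the endothelial (0.0264), G1/S (0.0363), alveolar type 1 and type 2 (both 0.000811) and amino acid response (3.49e-06) lists. Leaving out each library, ranges of adjusted p for lists that turned were 0.00327 to 0.766 (amino acid response, deficient against adequate), 5.52e-05 to 0.464 (alveolar type 2, deficient against adequate), 3.18e-08 to 0.801 (G2/M, deficient against adequate), 8.64e-06 to 0.461 (G2/M, supplemented against adequate), 0.000225 to 0.207 (amino acid response, deficient against restricted), 2.68e-05 to 0.391 (interferon, deficient against restricted), 2.13e-16 to 0.803 (endothelial, deficient against supplemented), 2.30e-11 to 0.169 (alveolar type 1, deficient against supplemented), 9.99e-08 to 0.94 (amino acid response, deficient against supplemented), 4.10e-09 to 0.169 (alveolar type 2, deficient against supplemented). The lists of the deficient comparisons turned without deficient replicate 3, the interferon list without restricted replicate 3, and the G2/M list of supplemented against adequate without adequate replicate 2. Depth limits genes with few counts. For Alb outside the adequate group the values argue against depth as the reason. Deficient replicate 1 and supplemented replicate 4 held 0 Alb counts among 29994300 and 26362700, and adequate replicate 2 held 259 among 18836100.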

Other observations

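The correlations with the lung list, the contrast of adequate with the other diets and the focus on fits without deficient replicate 3 were chosen after the data were seen. Among planned list tests not described so far, the p53 and apoptosis list was lower in restricted than in adequate libraries, with 22 of 27 members below 0 and a median of -0.42 (camera adjusted p = 0.000203, adjusted p = 0.159 with an estimated correlation). The glucocorticoid response list had a median of -0.50 in the same comparison with 14 of 20 members below 0 (camera adjusted p = 1.60e-05, adjusted p = 0.493 with an estimated correlation). The alveolar type 2 list was lower there too (median -0.58, camera adjusted p = 0.0178, adjusted p = 0.767 with an estimated correlation). Over the 15 libraries the glucocorticoid list went with it at r = 0.705 (permutation p = 0.00384, adjusted p = 0.0119, rho = 0.525, p = 0.0471, 0.437 without the 2 libraries farthest from the median), and with the lung covariate its camera adjusted p was 0.000351. The cholesterol synthesis list had a median of 0.44 with 20 of 23 members above 0 (camera adjusted p = 1.21e-06, adjusted p = 0.493 with an estimated correlation).

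Over the 15 libraries, 31 list levels were correlated with the alveolar type 2 list. Immune lists rose with it: B and plasma cells at r = 0.834 (permutation p = 0.00019, adjusted p = 0.00196, rho = 0.871, p = 7e-05), macrophages at 0.802 (p = 0.00032, adjusted p = 0.00248, rho = 0.771, p = 0.00139) and T and NK cells at 0.766 (p = 0.00095, adjusted p = 0.00491, rho = 0.782, p = 0.00105). Without the 2 libraries farthest from the median r was 0.861, 0.782 and 0.825. The macrophage and alveolar type 2 lists share the gene Lyz2. The G2/M list went the other way at r = -0.706 (p = 0.00542, adjusted p = 0.014, rho = -0.761, p = 0.00146, -0.691 without the 2 libraries), and within diets at -0.681. The melanocyte pigment list showed no such relation (r = 0.167, p = 0.557, adjusted p = 0.664, rho = 0.236, p = 0.397), nor did the interferon list (r = 0.151, p = 0.591, rho = 0.161, p = 0.568).

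Averaged against the other 3 diets, the adequate libraries differed in 13 genes by edgeR's adjusted p, a contrast added after seeing the data. Higher were Klf15 (log2 fold change 1.31, adjusted p = 0.0189), Pccb, a subunit gene of propionyl-CoA carboxylase that acts downstream of methionine breakdown (0.73, adjusted p = 0.0285), and the cold-inducible RNA-binding protein gene Cirbp (1.72, adjusted p = 0.0332). Cirbp stood at 41.3 and 44.7 CPM in adequate replicates 2 and 3, but at 13.7 CPM in adequate replicate 1, within the range of the other diets (5.92 to 17.8 CPM). Ddr2 (-1.03, adjusted p = 0.0189), Mfsd12 (-1.01, adjusted p = 0.0207) and Tap2 (-0.86, adjusted p = 0.0482) were lower. These genes were named after their values were seen.

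The amino acid response list in the deficient group turned from near 0 to higher when deficient replicate 3, the library richest in lung markers, was left out (camera adjusted p = 9.99e-08 against supplemented, adjusted p = 0.624 with an estimated correlation), with 37 of 45 members above 0. Left out in turn, deficient replicates 1 and 2 gave the other direction against supplemented (camera adjusted p = 0.0248 and 0.0195). Its levels were 6.27, 6.29 and 5.41 in the deficient libraries and 5.49 to 6.54 in the supplemented, so the groups overlap. A hypothesis is that lung tissue may mask a response of the tumour cells in that library. With the lung covariate the camera adjusted p was 0.0252 against restricted, and 0.0559 against supplemented and 0.529 against adequate, so the comparisons do not bear it out together.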
